A study of Homo sapiens with 4 samples.

How the data were processed

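RNA was sequenced from the human colorectal cancer cell lines DLD-1 and HCT-116, each as an empty-vector control line and as a line with a knockout of the serine racemase gene SRR, per the labels. There was 1 library per group and 4 libraries in all. Per the labels' protocols, total RNA was extracted with a column kit that retains small RNA, and libraries were made with a stranded, poly(A)-selecting mRNA kit. How the knockout was made, whether a knockout line was a single clone or a pool, and how long the cells had been kept apart from their controls are not given in the sources used here.

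The deposited values are FPKM per gene symbol, 23284 symbols per library, as the authors deposited them. Per the submitters' processing notes, the tools used were TopHat2 2.0.13, Bowtie2 2.2.3, SAMtools 0.1.19 and Cuffnorm 2.2.1, with the human genome build hg19. The gene annotation and the normalization setting of Cuffnorm are not given in the sources used here. FPKM divides a gene's fragments by its length and by the sequencing depth, so short genes with few fragments can carry large values. Among the 23284 symbols, 1618 belong to small RNA classes (microRNA, small nucleolar, small nuclear, Y, 7SL, vault and 5S RNA), which held 15.3% to 19.5% of each library's summed FPKM. These were left out of the main analysis and kept in an alternative.

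The files state no read numbers. Low FPKM values of a gene stood in whole-number ratios between libraries, so the worth of 1 read relative to the HCT-116 control was taken from the most frequent ratio among values under 0.5 FPKM, and gave relative depths of 1.07 for the DLD-1 control, 1.01 for the DLD-1 knockout, 1.00 for the HCT-116 control and 1.06 for the HCT-116 knockout. Of 3872 genes of low to middle level with a value above 0 in every library, 2827 (73.0%) came out as whole multiples of a common step within a tolerance of 0.02 of a read, against 3.23% after the values had been jittered. An absolute depth of about 8960000 fragments for the DLD-1 control, 8430000 for the DLD-1 knockout, 8340000 for the HCT-116 control and 8830000 for the HCT-116 knockout was estimated from 146 genes of at least 2000 bases with a single RefSeq-linked transcript in the GENCODE reference. The estimates from single genes had an interquartile range of 4440000 to 8740000 for the HCT-116 control, so fragment numbers are approximate. Intervals given for SRR are exact conditional Poisson intervals at 95% and cover counting error only.

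For each cell line, a gene's change is log2((knockout FPKM + 1)/(control FPKM + 1)), a scale that understates the change of low genes. Genes with at least 1 FPKM in either library of the line were analysed. With 1 library per group no test between knockout and control was possible within a line, so genes were counted by size, at least 2-fold higher or lower, and no p-value is given for them. The lines were compared by the number of genes past the 2-fold rule in both, beside the number expected of independent lists, and by the correlation of fold changes across genes. An effect common to both lines was tested with limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with a mean-variance trend, the cell line as a block, 1 residual degree of freedom, and Benjamini-Hochberg adjustment at 0.05. The block rests on the cell line named in the labels, since each knockout has its own control of the same line.

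40 gene lists were fixed before the data were examined, as were the measures, filters and thresholds above. A list with at least 5 analysed members was described per line by its median log2 fold change and by the percentile of that median among 10000 random lists of the same size drawn from the same 20 bins of mean expression. A list is said to stand apart below the 2.5th or above the 97.5th percentile. The percentile describes these libraries and is no test of the knockout. Older symbols were matched through the reference's name tables.

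The genes named in the text were set by a rule. It takes SRR, and for each line the 10 genes highest and the 10 lowest in log2 fold change among genes with at least 5 FPKM in either library, leaving out symbols that begin with LOC or LINC and readthrough symbols that join a pair of listed genes. It also takes the 10 higher and 10 lower genes with the largest smaller change in both lines, under the same exclusions and with at least 5 FPKM in either library of each line, the 5 genes each way that moved most in opposite directions, and up to 4 members per list and line with a log2 fold change of at least 1 in size. Other members of a list are named with their values as examples of that list; these, and the genes of chromosome 17 and of the HOXA cluster, were chosen after their values were seen. Some genes that the rule takes are not reported here.

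The order of genes along chromosomes was taken from the RefSeq gene table of assembly GRCh38.p14. The files use another build, so no coordinates are given. Runs of neighbouring protein-coding genes were compared by their median log2 fold change with all runs of as many analysed genes on any chromosome.

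Alternatives changed 1 choice at a time: pseudocounts of 0.1 and 0.01, no filter on low values or a filter of 5 FPKM, each library scaled to the same sum, fold changes centred on their median, quantile normalization, small RNA genes kept, thresholds of 1.5-fold and 4-fold, limma without the cell line, without the trend or with robust estimation, and random lists not matched on expression. The trend with transcript length, GC content and expression level was removed with polynomials of degree 3 over the genes with a length and GC content, 95.8% of the analysed genes in each line.

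The steps were tested on simulated data, with Poisson fragments for the real genes at a depth like that of the libraries and 200 genes changed by known folds. Among 11146 genes simulated for DLD-1, the 2-fold rule found 88.0% of 50 genes changed 2.5-fold, 96.0% of 50 changed 4-fold and 0 of 50 changed 1.5-fold, and called 1 of 10946 unchanged genes. Among 11484 genes simulated for HCT-116, it found 84.0% of 50 genes changed 2.5-fold and all 50 changed 4-fold, and called 3 of 11284 unchanged genes. In the limma fit over both simulated lines (10413 genes), 94.0% of 50 genes changed 1.5-fold and all 50 changed 2.5-fold had an adjusted p under 0.05, as did 28 of 10213 unchanged genes. These figures hold for counting noise alone, without the differences that separate real cultures. Of 200 lists of 20 unchanged genes simulated for DLD-1 among 11146 genes, 3.50% stood apart. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.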

Results

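RNA levels were measured by poly(A)-selected RNA sequencing in the colorectal cancer cell lines DLD-1 and HCT-116, each with an empty-vector control and an SRR knockout, with 1 library in each of the 4 groups. SRR encodes serine racemase, the enzyme that interconverts L-serine and D-serine and can also convert serine to pyruvate. No group had a replicate, so every difference below is between single libraries and has no replicate check. The summed FPKM was 707882 in the DLD-1 control, 692037 in the DLD-1 knockout, 756920 in the HCT-116 control and 816899 in the HCT-116 knockout. The steps between low values put the depths within 1.07 times of each other, at an estimated 8340000 to 8960000 fragments, and between 11523 and 11935 genes per library reached 1 FPKM.

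SRR itself, the gene targeted per the labels, was lower in both knockout libraries but was not at 0 in either. In DLD-1 it was at 1.65 FPKM in the control and 0.853 FPKM in the knockout, a log2 fold change of -0.52. In HCT-116 it was at 2.78 FPKM in the control and 0.724 FPKM in the knockout, a log2 fold change of -1.13. The values correspond to 37 and 18 reads in DLD-1 and to 58 and 16 reads in HCT-116. The knockout level was 51.7% of the control in DLD-1 (exact 95% interval 27.7% to 93.1%) and 26.1% in HCT-116 (13.99% to 46.0%). Neither the edit of the gene nor its protein was measured in these libraries.

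The genes around SRR on chromosome 17 differed between DLD-1 knockout and control as a block. Of the 21 analysed protein-coding genes between the end of the short arm and SRR, 20 were lower in the knockout, with a median log2 fold change of -0.68. YWHAE, which encodes a 14-3-3 protein, was at 579 FPKM in the control and 345 FPKM in the knockout. PRPF8, a core component of the spliceosome, was at 123 and 70.2 FPKM, and RPA1, a subunit of the single-stranded DNA binding complex, at 54.7 and 28.5 FPKM. NXN, MYO1C, CRK, GLOD4 and SMG6 were lower too, with log2 fold changes of -0.97, -0.61, -0.67, -0.74 and -0.84. DPH1 was the 1 gene above 0, at 0.20. On the other side of SRR the direction turned: TSR1, the next gene, was at 54.9 FPKM in the control and 79.8 FPKM in the knockout, and SGSM2 at 9.86 and 17.6 FPKM. From TSR1 to the end of the short arm, 146 of 177 genes were higher in the knockout, with a median log2 fold change of 0.29. On the long arm the median over 480 genes was -0.01. Among genes with at least 5 FPKM, the knockout level had a median of 59.4% of the control between the arm's end and SRR and 123% from TSR1 to the end of the arm. The interval of SRR in DLD-1 takes in the median of its neighbours on the side of the arm's end.

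HCT-116 showed no block of that size. The median was -0.10 over 29 genes between the arm's end and SRR, -0.04 over 172 genes from TSR1 to the end of the arm and -0.02 over 506 genes of the long arm, while SRR stood at -1.13. In DLD-1, 4 of 10505 runs of 21 neighbouring genes had a median as low as that of the block next to SRR, itself included, and the lowest run on any other chromosome was at -0.43. In HCT-116, 58 of 10614 runs of 29 genes were as low as its block, and 681 of 10526 after the trend with length, GC content and expression had been removed. The list of SRR's nearest neighbours fixed before the data were examined, which takes genes from both sides of SRR, had a median of 0.15 in DLD-1 at percentile 93.7 and did not stand apart. The stretches were chosen after the values had been seen, and no DNA was measured.

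**Figure D1:**
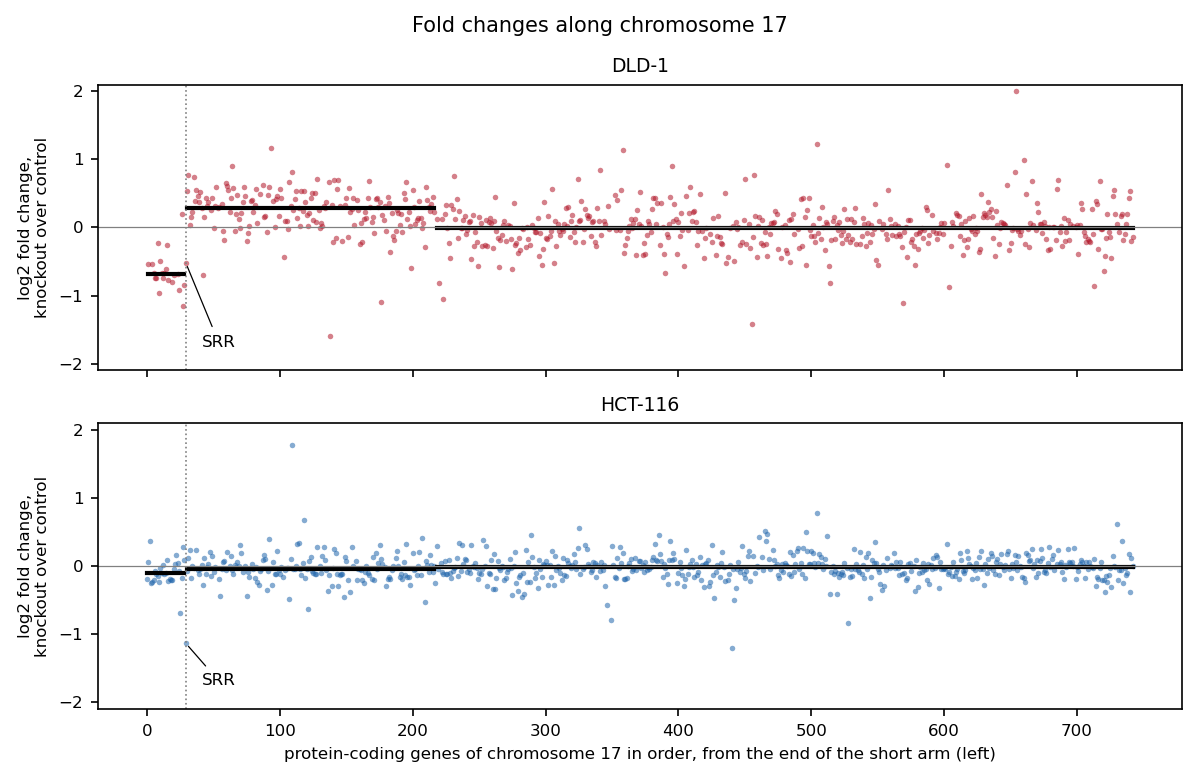
Log2 fold change (knockout over control, pseudocount 1) of each analysed protein-coding gene of chromosome 17, in gene order from the end of the short arm; points are genes, black lines the medians of the 3 stretches, and the dotted line marks SRR. In DLD-1 the line steps from -0.68 before SRR to 0.29 after it and to -0.01 on the long arm, and in HCT-116 it runs at -0.10, -0.04 and -0.02.

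The knockout in DLD-1 was compared with its control to ask which transcripts differed between the libraries. Genes of cholesterol synthesis were lower and genes of the NF-kB and chemokine list were higher in the knockout. Of the 24 cholesterol synthesis genes driven by the transcription factor SREBP2, 23 were below 0 and 18 were at least 1.5-fold lower. SQLE, which encodes squalene epoxidase, was at 53.7 FPKM in the control and 18.7 FPKM in the knockout. INSIG1, whose product holds the SREBP precursor in the endoplasmic reticulum, was at 39.5 and 15.4 FPKM, and the sterol oxidase MSMO1 at 61.6 and 29.8 FPKM. SCD, the desaturase that makes oleate, was at 153 and 33.9 FPKM, among the 10 lowest genes of the comparison.

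The list's median in DLD-1 was -0.77, below all 10000 random lists, 95% of which lay between -0.10 and 0.10. HMGCS1, an early enzyme of the pathway, had a log2 fold change of -0.82. DHCR7, CYP51A1 and SC5DL, late enzymes, had -1.004, -0.97 and -0.97. The fatty acid synthesis list had a median of -0.20, with FASN at -0.45, ACACA at -0.55 and ELOVL6 at 0.44.

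Of 18 analysed genes on the NF-kB and chemokine list, 17 were above 0 in DLD-1 and 10 were at least 1.5-fold higher, with a median of 0.60, above all random lists. LCN2, an iron-binding secreted protein, was at 71.6 FPKM in the control and 319 FPKM in the knockout. IL8 was at 10.1 and 36.4 FPKM, CXCL1 at 4.63 and 13.99 FPKM, and CCL20 at 21.5 and 46.9 FPKM, all neutrophil or lymphocyte attractants. PLAU, the urokinase plasminogen activator, was at 2.68 and 6.94 FPKM. PTGS2, the inducible cyclooxygenase, which is outside the list, was at 0.40 and 6.18 FPKM. ICAM1 was the 1 member below 0, at -0.22. The MAPK and immediate early list stood apart on the high side as well, with a median of 0.23. Its DUSP5, a phosphatase of ERK, was at 21.1 and 54.3 FPKM, and the EGFR ligand AREG at 14.2 and 33.4 FPKM.

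Stress lists went in different directions in DLD-1. The unfolded protein response list had a median of -0.31, with 18 of 20 members below 0, HSPA5 at -0.55 and HSP90B1 at -0.51. All 15 heat shock genes analysed were below 0, with a median of -0.24, HSPB1 at -0.74 and HSPH1 at -0.71. The amino acid response list driven by ATF4 had a median of 0.29, with 19 of 23 members above 0. ASNS, asparagine synthetase, was at 53.5 FPKM in the control and 115.5 FPKM in the knockout, and the secreted stress factor GDF15 at 170 and 319 FPKM. The serine and glycine synthesis and one-carbon list, the pathway nearest to serine racemase, had a median of 0.007 at percentile 65.3, and the list of D-amino acid and serine transport had -0.088 in DLD-1 and -0.081 in HCT-116, within the range of random lists in each. On the serine and one-carbon list PHGDH, the first enzyme of serine synthesis, was at 64.1 and 111 FPKM, PSAT1 at 129 and 132 FPKM, and the folate enzyme ALDH1L1 at 5.41 and 1.92 FPKM.

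Other lists stood apart in DLD-1 as well. Glycolysis had a median of -0.20, with LDHA at -0.69 and PFKP at -0.52, and the housekeeping list -0.12. On the high side were replication-dependent histones at 0.61, metallothioneins at 0.54, secretory differentiation at 0.47, EGFR ligands and receptors at 0.24 and antigen presentation at 0.23. Mitosis genes had a median of 0.17 with 26 of 28 above 0, autophagy and lysosome 0.17, NRF2 targets 0.13, the TCA cycle 0.09 and the nuclear-encoded respiratory chain 0.07. In all, 6 lists stood apart on the low side and 13 on the high side, of 36 with at least 5 analysed members. For lists of randomly drawn genes, 1.80 would fall outside the limits. Genes of the same list can vary together between any cultures, and AREG is on both the MAPK and the EGFR lists. The excess over 1.80 is therefore no measure of a knockout effect. Under at least 1 alternative, metallothioneins, secretory differentiation, EGFR ligands and receptors, antigen presentation, the TCA cycle, the respiratory chain and housekeeping came within the range of random lists. The first 3 of these lists had a median of 0 when low genes were not filtered. Of their members, 5 of 9, 6 of 23 and 8 of 14 reached 1 FPKM, so members at or near 0 FPKM drew the median there. Replication-dependent histone mRNAs mostly lack a poly(A) tail, so their levels in such libraries are uncertain, in HCT-116 too. Among the cell cycle inhibitors of the p53 list, CDKN1A was at 12.2 and 31.6 FPKM, while the list's median of 0.08 lay within the range of random lists.

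Single members of lists that stood within the random range or had small medians also passed 2-fold in DLD-1: the tight junction gene CLDN2 at 4.07 and 9.28 FPKM and MAP1LC3A, an autophagosome protein, at 0.98 and 6.20 FPKM. Beyond the lists, NPNT, an extracellular matrix protein, was at 15.1 FPKM in the DLD-1 control and 2.58 FPKM in the knockout, and NETO2, an auxiliary subunit of kainate receptors, at 33.9 and 6.78 FPKM. TUBA4A, an alpha-tubulin, was at 189 and 62.1 FPKM, GNE, the first enzyme of sialic acid synthesis, at 14.3 and 4.35 FPKM, the receptor phosphatase PTPRU at 11.5 and 3.34 FPKM, and the sodium-proton exchanger SLC9A2 at 6.23 and 1.09 FPKM. KLHL35, CRYBB3 and TERC had log2 fold changes of -1.83, -1.61 and -1.77; TERC has no poly(A) tail, so its level in such a library is uncertain. On the high side, SGPP2, a sphingosine-1-phosphate phosphatase, was at 2.86 and 16.7 FPKM, MXRA7 at 1.02 and 8.805 FPKM, EEF1A2 at 0.87 and 6.19 FPKM, CIB2 at 0.83 and 6.75 FPKM, and PRR9 at 0.79 and 6.11 FPKM. SH3BGRL and LARP6 were listed at 0 in the control and at 13.6 and 5.23 FPKM in the knockout. H3F3A was at 10.5 FPKM in the DLD-1 knockout and 0.01 FPKM in every other library, although all proliferating cells use this histone, and near-identical copies of it exist, so its values are uncertain.

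In DLD-1, 142 genes were at least 2-fold higher and 105 at least 2-fold lower, 2.11% of 11723 analysed. Of these, 14 of the higher genes were listed at 0 in the control and 9 of the lower genes at 0 in the knockout, and without genes listed at 0 or sharing exons with a readthrough model 119 were higher and 91 lower. The difference has no replicate check.

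The same comparison in HCT-116 gave fewer and smaller differences. Immediate early genes were higher in the knockout, and the cholesterol and fatty acid synthesis lists were again on the low side, by much less than in DLD-1. FOS was at 18.0 FPKM in the control and 77.8 FPKM in the knockout, FOSB at 1.13 and 9.32 FPKM, and EGR1 at 24.2 and 56.9 FPKM, all transcription factors induced within minutes of growth factor signals. IGF2BP3, an oncofetal RNA-binding protein, was at 19.8 and 6.16 FPKM, and ADAM19, a membrane protease, at 18.8 and 7.56 FPKM.

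The MAPK and immediate early list had a median of 0.11 in HCT-116, with 18 of 24 members above 0 and 3 at least 1.5-fold higher. The cholesterol synthesis list had a median of -0.09 at percentile 0.16, with 17 of 24 members below 0 and none at least 1.5-fold lower. INSIG1 was at 50.2 and 35.7 FPKM, SQLE at 51.7 and 44.3 FPKM, and STARD4 had a log2 fold change of -0.39. The fatty acid list had a median of -0.13, with FASN at -0.31 and SCD at -0.23. Genes of ribosome biogenesis had a median of -0.09, with 24 of 25 below 0, among them MYC at -0.19 and NOLC1 at -0.28, while 40 of 41 cytosolic ribosomal protein genes were above 0, with a median of 0.11 that turned to -0.01 under quantile normalization. The WNT and intestinal stem cell list was at -0.13, mitochondrial biogenesis at -0.080, glycolysis at -0.046 and NRF2 targets at -0.046. Replication-dependent histones were at 0.34, with HIST1H2BJ listed at 0 in the control and at 1.13 FPKM in the knockout, NF-kB genes at 0.21, antigen presentation at 0.12, interferon response at 0.11 and autophagy and lysosome at 0.07. Of the 7 NF-kB genes analysed, 4 were above 0 and 3 below. Glycolysis, mitochondrial biogenesis, NRF2 targets, ribosomal proteins, interferon response, NF-kB genes, histones and autophagy did not stand apart in HCT-116 under at least 1 alternative, NF-kB genes and histones with a median of 0 when low genes were not filtered. Only 7 of 24 NF-kB and 7 of 18 histone members reached 1 FPKM there. Members at or near 0 FPKM, whose change is near 0 on this scale, set that median. With a pseudocount of 0.1 these lists still stood apart, at percentiles 99.9 and 98.65. After removal of the trend with length, GC content and expression, WNT genes (percentile 4.04), mitochondrial biogenesis (2.97), NRF2 targets (14.2), ribosomal proteins (91.5, median 0.018) and autophagy (95.8) lay within the range of random lists. Heat shock (percentile 1.27, median -0.074) and the nuclear-encoded respiratory chain (97.9, median 0.027) came to stand apart in HCT-116 after that removal, on the sides they had in DLD-1.

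The interferon-induced IFIT1 was at 1.25 and 4.35 FPKM in HCT-116, and BST2 at 0.30 and 1.83 FPKM. The serine and one-carbon list had a median of -0.018 at percentile 23.5, with PHGDH at 131 and 130 FPKM. In all, 7 lists stood apart on each side of 35 with enough members. For lists of randomly drawn genes, which do not vary together as list members can, 1.75 would. Scaling each library to the same sum moved the median of all HCT-116 genes to -0.10, so values under it are read relative to that shift. The autophagy list turned to -0.041 under it, above the shift, and no other list that stood apart changed sign under it.

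Other genes high in the HCT-116 knockout were the transcription factor ZBED2 at 2.56 and 16.9 FPKM, NETO2 at 1.51 and 7.82 FPKM, and FGFBP1, which releases fibroblast growth factors from the matrix, at 6.33 and 18.4 FPKM. Low genes were SULT1A1, a sulfotransferase with near-identical paralogs, at 15.6 and 6.76 FPKM, ARHGAP29 at 35.7 and 16.5 FPKM, the serotonin receptor HTR7 at 6.99 and 3.06 FPKM, SYNJ2 at 7.31 and 3.39 FPKM and the mitochondrial carrier UCP2 at 8.54 and 4.07 FPKM. PLSCR3, BSCL2 and PRR4 had log2 fold changes of 1.78, 1.45 and -1.27 and share exons with a readthrough model. PLSCR3 was at 4.75 and 18.7 FPKM while the model that joins it to C17orf61 was at 19.1 and 3.10 FPKM. SNAR-E and HSP90AA6P were listed at 0 in the control, and RMRP and DEFB109P1 at 0 in the knockout. RMRP and DEFB109P1 had only about 14 and 12 fragments in the control, so their changes are uncertain. SNAR-E, at 43.1 FPKM in the knockout, is not in the small RNA classes that were left out. No fragment number was estimated for SNAR-E or HSP90AA6P, so the counting error of their changes is not known. The pseudogene AQP7P3 had a log2 fold change of 1.60.

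In HCT-116, 41 genes were at least 2-fold higher and 28 at least 2-fold lower, 0.573% of 12044 analysed. Of these, 12 of the higher genes were listed at 0 in the control and 11 of the lower genes at 0 in the knockout. Without genes listed at 0 or sharing exons with a readthrough model, 24 were higher and 11 lower. With each library scaled to the same sum the split was 41 higher and 44 lower.

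**Figure D2:**
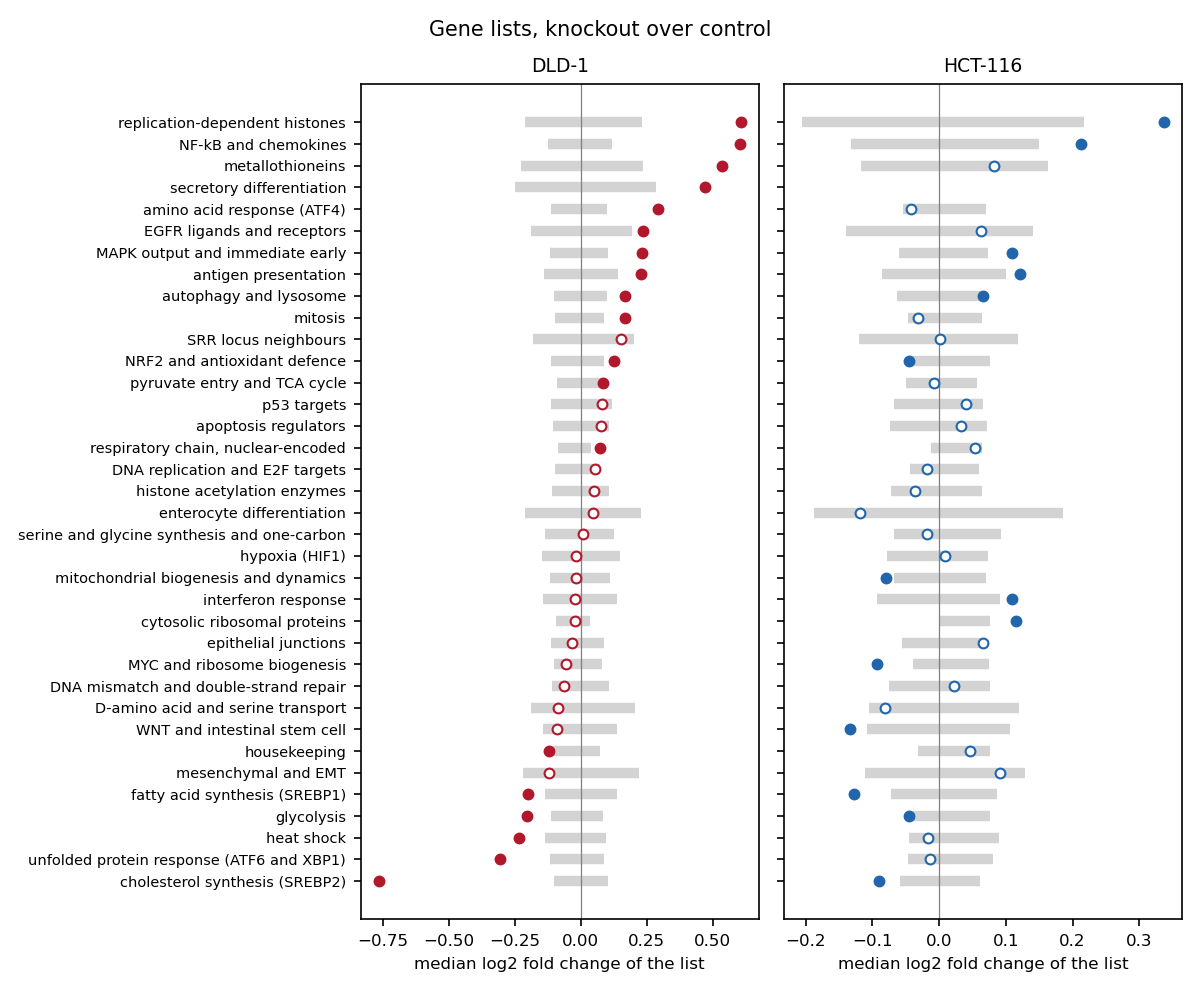
Median log2 fold change (knockout over control) of each gene list with at least 5 analysed members in DLD-1 and HCT-116; grey bars span the middle 95% of 10000 random lists of the same size and expression, and filled points stand apart. The axes differ: cholesterol synthesis lies at -0.77 in DLD-1 and -0.09 in HCT-116.

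Comparing the lines asks whether the same transcripts differed between knockout and control in both. At least 2-fold higher in both were HIST1H2AC, of the replication-dependent histone list, and the readthrough model SERF2-C15ORF63, 2 genes where 0.194 would be expected of independent lists. The readthrough model HOXA10-HOXA9 was at least 2-fold lower in both, 1 gene where 0.0606 would be expected, and was listed at 0 in both knockouts. In opposite directions, 3 genes were lower in DLD-1 and higher in HCT-116, where 0.133 would be expected, and 1 was higher in DLD-1 and lower in HCT-116, where 0.0882 would be. Without genes listed at 0 in the line or sharing exons with a readthrough model, an alternative chosen after the values had been seen, 0 genes were higher in both, 0 lower in both and 2 opposite, and with a filter of 5 FPKM the numbers were the same. Smaller pseudocounts raised the numbers, to 7 higher in both, 8 lower in both and 10 opposite with 0.1, and to 8, 8 and 11 with 0.01. HIST1H2AC was at 2.996 and 8.60 FPKM in DLD-1 and was listed at 0 in the HCT-116 control and at 2.13 FPKM in its knockout. Below the 2-fold rule, GALNT5, which starts mucin-type glycosylation, had log2 fold changes of 1.40 in DLD-1 and 0.92 in HCT-116, and CRABP2, a retinoic acid carrier, 0.92 and 0.91. By the plain ratio of FPKM, GALNT5 was at 3.67 times the control in DLD-1 and 2.005 times in HCT-116. Only the pseudocount of 1 put it below the rule.

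CYR61, a secreted target of YAP, had 1.01 and 0.65, SEMA3B 1.29 and 0.58, JUNB 0.57 and 0.76, CARD10 0.49 and 0.49, and IGFBP6 0.70 and 0.46. COMMD3 had 1.39 and 0.52 and shares exons with a readthrough model that joins it to BMI1. In DLD-1 both genes and the model were higher in the knockout, with a summed FPKM of 52.8 and 132. A division of reads alone would not give that. In HCT-116 the sum was 46.8 and 60.9, with BMI1 lower. Lower in both was UCP2, at -1.37 and -0.91, chosen after its values were seen because its 4.86 FPKM in the DLD-1 control lay under the limit of the rule for shared genes. It was at 1.27 FPKM in the DLD-1 knockout. Within that limit, lower genes were EFNB2, a ligand of Eph receptors, at -0.74 and -0.64, the chaperone HSPH1 at -0.71 and -0.55, the secretory granule genes VGF at -1.10 and -0.51 and CPE at -1.43 and -0.51, and INSIG1 at -1.31 and -0.48. KANK1, FAM216A, DEAF1, ATF5 and C19orf71 followed, with the smaller of the changes between -0.43 and -0.50. Lists low in both lines were glycolysis, cholesterol synthesis and fatty acid synthesis. Lists high in both were antigen presentation, NF-kB, MAPK and immediate early, replication-dependent histones, and autophagy and lysosome. Under every alternative tried, cholesterol synthesis, fatty acid synthesis and the MAPK list stood apart in both lines, and the others named here did not in at least 1 line. Dropping the filter could not test NF-kB genes and histones in HCT-116, since most of their members were under 1 FPKM there.

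Across 10885 genes analysed in both lines, the fold changes had a Pearson correlation of 0.084 and a Spearman correlation of 0.093, over genes that are not independent replicates, and 52.8% of genes had the same sign. The correlation was -0.053 over 10984 genes when small RNA genes were kept, a difference that comes from the added genes alone. Of 46 genes at least 1.5-fold changed in both lines, 28 moved the same way. The controls of the lines differed from each other at least 2-fold in 1918 of these genes. In limma with the cell line as a block, 0 genes were higher and 0 lower at an adjusted p of 0.05, with a smallest adjusted p of 0.863. At an unadjusted p under 0.05 were 559 of the 10885 genes, near a share of 0.05. Changes unrelated between the lines would give about such a share, as would no effect. The share therefore cannot tell these apart. The spread in limma comes from 1 residual degree of freedom per gene, the difference between the lines in the knockout change. It was moderated across genes with a weight of 4.11 degrees of freedom. Other tools were not run.

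**Figure D3:**
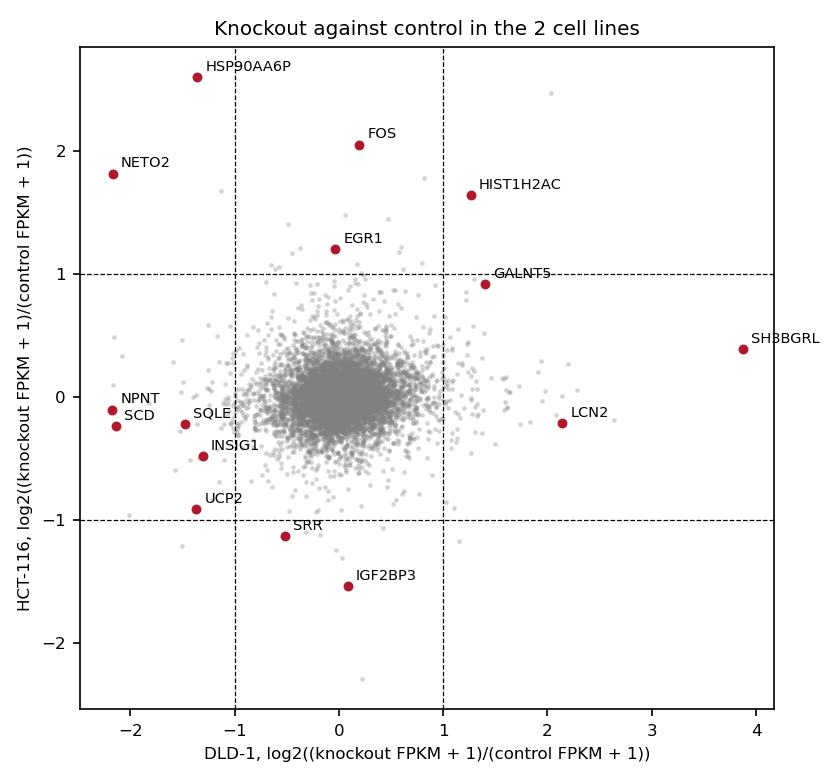
Log2 fold change (knockout over control, pseudocount 1) in DLD-1 against HCT-116 for the 10885 genes analysed in both; grey points are genes, red points are named, and dashed lines mark 2-fold. The cloud has a correlation of 0.084, and NETO2 lies at -2.17 in DLD-1 and 1.82 in HCT-116.

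The study's design text gives 1571 genes lower in knockout DLD-1 and 977 in knockout HCT-116, with no rule for the count. With no filter and no pseudocount, a ratio of FPKM of at most 0.5 was met by 1488 genes in DLD-1 and 1230 in HCT-116, while 1584 and 1222 genes were at least 2-fold higher. Among genes with at least 1 FPKM in either library, 314 and 132 genes were lower by that ratio. The rule behind the stated counts is not given in the sources used here.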

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

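No test between the lines was possible for the values of this part, so each difference in direction is untested, and the part reports no test chosen after the results were seen. Genes that were at least 2-fold changed in opposite directions in DLD-1 and HCT-116 were NETO2, at -2.17 and 1.82 on the log2 scale, BGLAP at -1.13 and 1.67, the pseudogene HSP90AA6P at -1.36 and 2.60, and the antisense transcript AKIRIN2-AS1 at 1.15 and -1.18. The next genes by the smaller change in opposite directions, not 2-fold in both lines, were C6orf141 at 1.102 and -0.90, TNFRSF6B at 1.02 and -0.85, RPL23AP64 at 0.77 and -0.79, C2orf89 at 0.90 and -0.64, C1orf182 at -0.70 and 0.94 and ANKRD22 at -0.65 and 0.65. BGLAP was listed at 0 in the DLD-1 knockout and the HCT-116 control and shares exons with a readthrough model, and HSP90AA6P was listed at 0 in the HCT-116 control. TNFRSF6B was listed at 0 in the DLD-1 control, had about 10 fragments in its knockout and shares exons with a readthrough model too. RPL23AP64, C2orf89 and C1orf182 had about 28 fragments or fewer in each library. NETO2 had about 2274 fragments in the DLD-1 control and 427 in its knockout, and 94 and 517 in HCT-116, so counting error is small beside its change. The list of NRF2 targets stood apart in opposite directions, with medians of 0.13 in DLD-1 and -0.046 in HCT-116. Its 3 analysed members highest in DLD-1 were NQO1 at 0.87, OSGIN1 at 0.69 and TXNRD1 at 0.65, and in HCT-116 these had 0.28, -0.056 and 0.16. In HCT-116 the list did not stand apart under every alternative. Small RNA genes are outside the main measurement, since they were left out of the comparisons, and they summed to 159102 FPKM in the HCT-116 knockout against 123939 FPKM in its control, and to 105902 against 119222 FPKM in DLD-1.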

How the results depend on the processing

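Chosen after seeing the data were 3 alternatives: no filter together with a pseudocount of 0.01, leaving out genes listed at 0 in the line or sharing exons with a readthrough model, and leaving out the short arm of chromosome 17. All others were planned. Counts of genes depended on the pseudocount, the filter and the threshold, by construction, and the values below run in the order higher in DLD-1, lower in DLD-1, higher in HCT-116, lower in HCT-116, higher in both lines, lower in both lines and opposite. They were 142, 105, 41, 28, 2, 1 and 4 as reported. A pseudocount of 0.1 gave 278, 243, 110, 82, 7, 8 and 10, and 0.01 gave 308, 264, 123, 96, 8, 8 and 11. A filter of 5 FPKM gave 85, 67, 18, 8, 0, 0 and 2. A threshold of 1.5-fold gave 538, 448, 164, 116, 17, 11 and 18, and 4-fold gave 12, 7, 6, 4, 1, 0 and 0. No filter with a pseudocount of 0.01 gave 1418, 1413, 1152, 1066, 198, 207 and 370. Without genes listed at 0 or sharing exons with a readthrough model they were 119, 91, 24, 11, 0, 0 and 2. With small RNA genes kept they were 183, 150, 83, 62, 6, 9 and 20, and the correlation between lines was -0.053. That alternative had 10984 genes analysed in both lines in place of 10885 and changed no other fold change. The added small RNA genes alone therefore gave these differences. Limma then called 3 genes higher and 4 lower in place of 0 and 0, and the cause of those calls was not tested. Scaling each library to the same sum gave 44 lower in HCT-116 and 3 lower in both lines. It moved the median of all HCT-116 genes to -0.10, and how far that shift gave these numbers was not tested. Without the short arm of chromosome 17 the counts were 140, 102, 40, 27, 2, 1 and 4. SRR in HCT-116 was at -1.93 with a pseudocount of 0.01, by the lesser damping of a low value, and at -1.80 with 0.1. Limma was not run for the 3 alternatives chosen later or for other fold thresholds. Under each other alternative it was run under it called 0 genes in each direction, and without the cell line block 9 genes had an unadjusted p under 0.05. Of 1392 values of named genes under the alternatives, 1304 stayed within counting error, 88 moved and 0 reversed. Dropping the filter, raising it to 5 FPKM or keeping small RNA genes leaves a gene's fold change as it is. The 174 values under each of these could therefore only stay. A changed pseudocount cannot reverse a sign, so the values under it could not reverse either. Of 19 lists that stood apart in DLD-1, 12 did so under all 9 alternatives, and of 14 in HCT-116, 6 did. In DLD-1 the TCA cycle, respiratory chain, secretory, antigen presentation, EGFR ligand and receptor, metallothionein and housekeeping lists lost their place. In HCT-116 glycolysis, mitochondrial biogenesis, NRF2, ribosomal proteins, interferon, NF-kB, histones and autophagy did. Without the filter, lists with many members under 1 FPKM are drawn toward a median of 0 by construction. Heat shock came to stand apart in HCT-116 under quantile normalization, on the low side at percentile 0.69 with a median of -0.12. With a filter of 5 FPKM the histone list had too few members in HCT-116 for a value. After removal of the trend with length, GC content and expression, housekeeping in DLD-1 was at percentile 9.01. Depth limits low genes: SRR rested on 16 to 58 reads per library, and BGLAP in DLD-1 on about 8 fragments in the control.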

Other observations

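The HOXA cluster on chromosome 7, whose genes set position along the body axis and keep a regional code in epithelia, was lower across its length in the DLD-1 knockout. All 11 analysed HOXA genes were below 0, from HOXA2 at -0.90 to HOXA7 at -0.30, with a median log2 fold change of -0.50. HOXA13, a marker of the distal colon, had -0.69, and HOXA9 had -0.43. In HCT-116, 8 members were analysed, with 3 below 0 and a median of 0.06. AGR2, a disulfide isomerase of mucus-secreting cells, was at 593 FPKM in the DLD-1 control and 381 FPKM in the knockout, while MUC13 was at 4.70 and 15.3 FPKM, SPINK4 at 1.26 and 5.37 FPKM and the tight junction gene CLDN1 at 3.43 and 12.97 FPKM. The mitochondrial-encoded respiratory genes were not analysed here, 2 immune and 1 fibroblast marker genes reached 1 FPKM in DLD-1, and the cancer-testis genes MAGEA3, MAGEB2 and PRAME were detected at 20 FPKM or more in HCT-116 only.

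The tests of overlapping gene models were chosen after the results were seen, the stretches of chromosome 17 were found in these data, and the reading of the scaling tests mainly by quantile normalization, the requirement that a result and its interval hold without the gene with the most fragments, and the reading of the correlation of sterol genes as open, were added after the results were seen, while the other tests of this part were set before.

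In the DLD-1 knockout, genes between the end of the short arm of chromosome 17 and SRR were low and those from TSR1 to the end of the arm high. Centring shifts all genes alike and cannot test such a pattern, and scaling to the same sum tests it weakly, while quantile normalization left medians of -0.68 and 0.28, as low in 3 of 10505 runs and as high in 2 of 7007 (nearest to 0 over the 3 scalings, -0.67 and 0.28). After removal of the trend with length, GC content and expression they were -0.68 and 0.25, which argues against that trend. A changed number of copies, a loss of the part beyond SRR with a gain of the rest of the arm, stays open: 16 genes of the first stretch not used to find it, non-coding or under 1 FPKM, had 68.2% of the control's fragments in the knockout (95% interval 51.6% to 89.4%), which meets the rule set before, but 77.7% without SLC43A2, the gene with the most fragments (56.5% to 106.8%). For the second stretch the value was 117% (103% to 133%), but 104% without DNAH2 (91.4% to 119%), and DNA, which was not measured, would be needed for either. The intervals of both stretches cover counting error only. Changes of DLD-1 genes with 10 to 100 fragments had a spread of 0.62, against 0.29 from counting, so these intervals are too narrow.

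For the sterol and inflammatory lists, scaling and the trend were tested as sources. The cholesterol list was at -0.75 in DLD-1 and -0.078 in HCT-116 after removal of the trend and at -0.79 and -0.10 after quantile normalization, and lay outside the range of random lists each time. The NF-kB list in DLD-1 was at 0.60 and 0.63, outside the range too (nearest to 0 over the 3 scalings, -0.74, -0.088 and 0.61 in the same order). Whether the same sterol genes were lowest in both lines stays open, at a correlation of 0.17 over 24 members (permutation p = 0.426, two-sided): a value within the permutations had been set to count against it, but so few members leave room for a moderate correlation. An effect of the knockout may lie behind these shifts as a hypothesis, but differences in cell density, medium or clone between single cultures were not tested.

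The counts of changed genes were set against counting noise. Among the 19655 genes with a known length, with no filter and a pseudocount of 0.01, Poisson draws around each gene's mean gave 54.3% of the 1219 lower genes seen in DLD-1 and 69.3% of the 892 in HCT-116, so noise may account for much of such counts but how much cannot be told apart at this depth. At 1 FPKM with a pseudocount of 1 the draws gave 1.79% of the 234 changed genes with a known length in DLD-1 and 6.84% of the 55 in HCT-116, which argues against counting noise there. Among genes with at least 5 FPKM, those in a readthrough pair made up 3.44 times the share in changed genes that they had in all such genes in DLD-1 (9 of 152 changed genes) and 9.39 times in HCT-116 (4 of 26). These counts take genes and models of the same locus separately, such as PLSCR3 and C17orf61-PLSCR3 in HCT-116. Among the 9 in DLD-1, COMMD3 and BMI1 rose together with the model that joins them, from a summed 52.8 to 132 FPKM. A division of reads alone would not give that rise. Such a division may account for the change at the PLSCR3 locus of HCT-116, whose summed FPKM was 139 in the control and 133 in the knockout. It may also account for BSCL2 and PRR4, for which no sum is given here.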
